A study of Homo sapiens with 18 samples.

How the data were processed

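RNA sequencing was done on 18 libraries from 6 patients, 1 region of each of 3 lung tissue types per patient. The types were histologically normal lung, adenocarcinoma in situ (AIS, a glandular lesion that has not invaded the surrounding tissue) and invasive adenocarcinoma. Regions were cut by laser capture microdissection, which excises chosen areas of a stained section under a microscope, from archived tissue that had been fixed in formalin and embedded in paraffin, per the labels' protocols. Fixation of this kind fragments RNA, and total RNA was amplified with NuGEN kits made for such material before paired-end Illumina sequencing, per the labels' protocols. No unique molecular identifiers were named, so that reads are not independent molecules. How captured areas were matched between patients was not given in the sources used here.

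The deposited signal values were the authors' normalized read counts for 23672 genes and 8258 long intergenic noncoding RNAs (lincRNAs), 1 column per library with no pooling. The submitters' processing notes named the human build hg19, GSNAP 2012-06-25, SAMtools, HTSeq and DESeq, without versions for the last 3 and without roles, options or annotation. In each column every value above 0 was a whole multiple of 1 step, so that whole reads were recovered for 307679 of 307679 gene values and 42785 of 42785 lincRNA values (100%, tolerance 1e-06 reads). The step gives each library's size factor, the number by which the read counts of a library were divided, and it was the same in both tables. The deposited FPKM values were, in each row, the normalized count multiplied by 1 constant over all 18 libraries. They therefore carry the same size factors and no other correction between libraries. Neither the strand setting nor the treatment of reads that match several places was given in the sources used here. Near-identical genes (CEACAM5 with CEACAM6, SFTPA1 with SFTPA2, HBA1 with HBA2, BTNL3 with BTNL8, the HLA class I genes) and overlapping or antisense genes are therefore uncertain. No coordinates were used, and features are named as in the deposited tables. A lincRNA name carries the symbol of a gene, and 41 lincRNAs followed a row of the gene table almost exactly (correlation above 0.99), so the tables are not independent. Features on chromosome Y and related features were left out (104 genes and 124 lincRNAs, 79 of the latter unnamed).

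Read totals in genes ran from 2226704 to 12563143 per library, with group medians of 6891109 for normal, 6472311 for AIS and 7196902 for invasive tissue. Read totals in lincRNAs ran from 280360 to 2092863. Bounds against a group with 0 reads were set at 3 reads over the group's 6 libraries. Intervals and bounds cover counting error only.

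The main test was limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), with a mean-variance trend, the patient as a fixed block and all 18 libraries in 1 fit, which left 10 residual degrees of freedom. Fold changes are on this scale, which understates the change of low genes. Features with a mean of at least 10 over the 18 libraries were tested, 14758 genes and 1070 lincRNAs. Benjamini-Hochberg adjustment was made within each table and comparison, with a threshold of 0.05. The patient block follows from the labels, which tie the 3 regions to a patient. In the data the same-patient correlation of deviations from the group means was above 0.1 in all 6 pairs of each comparison, with medians of 0.205 for AIS and normal, 0.178 for invasive and normal, and 0.475 for invasive and AIS. Read totals were also close within some patients (11963923 to 12563143 in patient 6, 9250810 to 10512308 in patient 5) but not in others (3431598 to 6455935 in patient 2). Shared depth or processing was not separated from the patient. A count model was not the main test because the deposited values were normalized. Quasi-likelihood tests in edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as alternatives. Other alternatives were pseudocounts of 0.5 and 5, no filter and a mean of at least 50, no block or a random effect for the patient, only the groups compared, library quality weights, quantile and TMM rescaling, FPKM values with a pseudocount of 0.1, no mean-variance trend, and each patient left out in turn.

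Gene lists of cell type markers and pathways, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members (30 lists) were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists. The red blood cell list had 3 tested members and no list test, and the mitochondrially encoded list had 0. The rule named, per comparison, the 10 genes with the highest rise and the 10 with the strongest fall (5 and 5 for lincRNAs) among those past the threshold with the same direction in all 6 patients. Where none qualified in a direction, the 3 with the smallest p were named. Up to 3 members with the smallest p were named per list. Genes named outside this rule were chosen after their values were seen. Chosen in that way were the comparisons between list scores, the fit without AIS replicate 2, alone and in edgeR, the removal of GC content and length trends, and the set of 16 genes whose group means and plots are given. List members passing the threshold are named in full where they number 5 or fewer, except for a few genes whose values are not reported here and which stay in the counts of their lists.

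The correlation expected between both comparisons with normal lung was also computed with no change and each patient's deviations from the group means kept together, by exchanging their signs per patient. The fitting steps were tested on simulated data, counts drawn for 14394 genes with no change between AIS and normal tissue. In the simulated comparison of invasive with normal tissue 10.9%, 66.0%, 84% and 91.5% of genes changed 2-, 4-, 8- and 16-fold were recovered. For invasive against AIS the shares were 23.9%, 74.5%, 90% and 95.7%. As AIS and normal tissue were simulated without a difference, the gap between these shares is not read as a difference in power. The shares do not carry over to the real comparison of invasive tissue with AIS. Calls among unchanged genes were 7 of 128 and 9 of 145, and 0 calls were made for AIS against normal. No pair of libraries of the same tissue type matched within sampling noise (chi-square per degree of freedom at least 27.8). Pairs across tissue types were not compared in this way. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for preparation, checks and plots.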

Results

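Gene and lincRNA expression was measured in 18 libraries, 6 each of normal lung, AIS and invasive adenocarcinoma, with 1 region of each type from each of 6 patients. Each library held between 2226704 and 12563143 reads in genes, and 15175 to 18868 genes had a read. MALAT1, an abundant nuclear noncoding RNA, took 6.80% ± 1.71 of the reads in genes in normal lung, 11.8% ± 6.02 in AIS and 11.998% ± 4.58 in invasive tissue (SD, n = 6 each). The first principal component held 20.5% of the variance and scored between -99.8 and -20.3 in the normal libraries, between 18.3 and 66.7 in the invasive libraries and between 28.0 and 56.6 in 5 of the AIS libraries. AIS replicate 2 stood apart, with a score of -126.69. In the same library the score of endothelial markers (mean log2 value over the list) was 8.38 against 5.86 to 6.84 in the other 5 AIS libraries. Its score of lung adenocarcinoma associated genes was 4.69 against 7.41 to 8.69. Unless a unit is named, changes below are log2 fold changes ± SE over 6 patients.

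**Figure D1:**
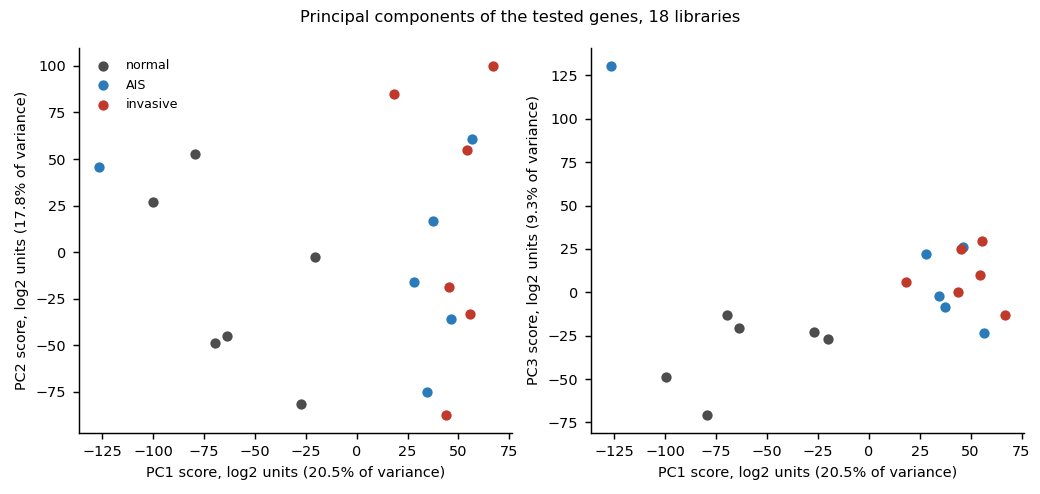
Scores of the 18 libraries (points, coloured by tissue type) on the first principal component against the second (left) and the third (right), in log2 units. AIS replicate 2 lies at -126.69 on the first and 130.67 on the third component, while the other 5 AIS libraries lie between 28.0 and 56.6 on the first.

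The comparison of AIS with normal lung of the same patients asks what distinguishes a lesion that has not invaded from histologically normal lung. CEACAM5, an adhesion glycoprotein carried by many gland-derived tumours, rose by 5.47 ± 0.82 (adjusted p = 0.00165, higher in 6 of 6 patients), from a mean normalized count of 115 ± 142 to 4743 ± 5419 (SD, n = 6). AGER, a receptor characteristic of the flat alveolar type 1 cells that carry gas exchange, fell by 2.56 ± 0.35 (adjusted p = 0.000979), from 14949 ± 6711 to 2907 ± 2554, and was lower in 6 of 6 patients. PECAM1, an adhesion protein of endothelial junctions, fell by 1.90 ± 0.22, and the receptor gene TEK, which binds angiopoietins on vessels, fell by 2.43 ± 0.29 (adjusted p = 0.000452 each). ABCC3, an export pump of epithelial cells, rose by 2.97 ± 0.20 (adjusted p = 4.27e-07). In limma 751 of 14758 genes passed the threshold, 281 higher and 470 lower (37.4% higher), and 3010 passed at an unadjusted p under 0.05. The number changed with the patients included. It was 1487 without patient 2, 552 without patient 4, 515 without patient 6, 346 without patient 1, 273 without patient 5 and 237 without patient 3. A fit with 1 patient fewer also has less power. Here and below, that loss was not separated from the part of the patient left out. It was 1377 (46.1% higher) when AIS replicate 2 alone was left out, 1736 in DESeq2 and 180 without the patient block.

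Of the genes named by the rule, GCNT3, an enzyme that branches mucin sugars, rose by 4.71 ± 0.92 (adjusted p = 0.0065), from a mean of 2.63 ± 3.97 to 123 ± 138 normalized counts. GYG2, which primes glycogen synthesis, rose by 4.41 ± 0.65 (adjusted p = 0.00165), and SPP1, which encodes the secreted matrix protein osteopontin, by 3.93 ± 0.69 (adjusted p = 0.00396). GSDMC of the gasdermin family (4.01 ± 0.77), FLRT1 (3.95 ± 0.63), the purine-degrading enzyme gene XDH (4.09 ± 0.83), the nicotinic receptor subunit gene CHRNA5 (4.09 ± 1.11), GLB1L3 (3.88 ± 0.81) and the chitinase gene CHIA (3.85 ± 0.82) completed the 10 highest rises. Among the falls, the serotonin transporter gene SLC6A4 fell by 4.00 ± 0.71 (adjusted p = 0.00426), from 1773 ± 996 to 175 ± 286 normalized counts. BTNL3, a butyrophilin-like gene, fell by 4.58 ± 0.80, although reads may be shared with BTNL8. C1orf140 had 215 reads in normal lung and 0 in AIS, a level at least 64.4-fold lower. SLITRK2, SERTM1, DPP6, the lectin gene ITLN2, the synapsin gene SYN2, the retinoid receptor gene RXRG and the collectin gene COLEC10 fell by 3.53 (COLEC10) to 4.48 (SLITRK2). All 20 genes changed the same way in 6 of 6 patients. Of these, 14 passed the threshold without any 1 patient and 12 under every alternative tried. The threshold was lost by XDH without patients 1 and 3 (adjusted p up to 0.0728), CHRNA5 without patients 1 to 5 (0.154), GLB1L3 without patient 3 (0.0662), CHIA without patients 1, 3, 4 and 5 (0.0747), DPP6 without patients 3, 5 and 6 (0.0947) and COLEC10 without patients 3 and 5 (0.0581). CHRNA5 also lost it in edgeR with either scaling, in the FPKM table, without a filter, a trend or the patient block, with 2 groups only and without AIS replicate 2, XDH and GLB1L3 in the FPKM table, and GLB1L3, CHIA, SPP1 and GSDMC without the block.

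In AIS 14 of 19 adenocarcinoma associated genes rose (17 adjusted over the list alone), with a median of 3.27. These included CEACAM6, an adhesion glycoprotein close in sequence to CEACAM5 (2.27 ± 0.27), and the Golgi membrane gene GOLM1 (1.78 ± 0.24). Of 24 general epithelial genes 6 rose (10 adjusted over the list alone), among them EPCAM, an epithelial adhesion molecule (2.08 ± 0.30), the tight junction gene CLDN4 (1.75 ± 0.30) and the splicing regulator gene ESRP1 (1.77 ± 0.31). Both lists passed camera at the preset correlation, but with adjusted p = 0.0677 with an estimated correlation for the adenocarcinoma list and adjusted p = 0.181 with an estimated correlation for the epithelial list. Of 20 alveolar type 2 markers, genes of the surfactant-making cells, 5 rose (6 adjusted over the list alone): NAPSA, a protease that processes surfactant protein (1.94 ± 0.35), LPCAT1, an enzyme of surfactant lipid (1.51 ± 0.36), the lung lineage regulator NKX2-1 (1.43 ± 0.36), the phosphate transporter gene SLC34A2 (1.45) and SFTA3 (1.22). For this list adjusted p = 0.603 with an estimated correlation. Of 18 lung cancer driver genes 3 rose, and the same number adjusted over the list alone: ERBB2 (1.11 ± 0.26), ROS1 (1.42 ± 0.39) and MDM2 (0.85 ± 0.24), with adjusted p = 0.181 with an estimated correlation. Without 1 patient the counts ran from 10 (patient 3) to 17 (patient 2) in the adenocarcinoma list, from 3 (patient 1) to 15 (patient 2) in the epithelial list, from 1 (patient 3) to 7 (patient 2) in the type 2 list and from 0 (patient 3) to 2 (patient 2) among the drivers. LPCAT1, NKX2-1 and ERBB2 each lost the threshold without patients 1, 3, 4 and 5 (adjusted p up to 0.11, 0.141 and 0.0926), ROS1 without patients 3 to 6 (0.178) and MDM2 without each patient but 4 (0.168). NKX2-1, ROS1 and MDM2 also lost it in edgeR with either scaling and without a trend, and ROS1 and MDM2 with TMM rescaling, in the FPKM table, without a filter, with the patient as a random effect and with 2 groups only. LPCAT1 was lost without a trend, and all 5 without the patient block. SLC34A2 was lost without patients 3 to 6 (0.157) and SFTA3 without patients 1, 3, 4 and 5 (0.156), both without a filter, a trend or the block, and SFTA3 in edgeR. In edgeR 1 of the drivers was called. Of the 51 called members named over the AIS lists 23 passed without any 1 patient and 18 under every alternative, while 31 were lost without the patient block, 16 without a trend, 10 without a filter and 7 in edgeR. Without AIS replicate 2, whose adenocarcinoma score lay nearest those of normal lung, 17 adenocarcinoma genes, 15 epithelial genes and 7 type 2 markers rose.

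Endothelial markers formed the list with the most falls. Of 24 members 19 fell (22 adjusted over the list alone), with a median of -2.002 and values down to -3.89 for GPIHBP1, a capillary protein that anchors lipoprotein lipase. CDH5, the cadherin of endothelial junctions, fell by 2.25 ± 0.30 (adjusted p = 0.000979). The list passed camera at the preset correlation and fry (adjusted p = 0.00066), with adjusted p = 0.0677 with an estimated correlation. Among 16 resident fibroblast markers 6 fell (10 adjusted over the list alone), such as the integrin gene ITGA8 (-1.67 ± 0.28) and the alcohol dehydrogenase gene ADH1B (-1.58 ± 0.28). Of 13 smooth muscle and pericyte markers 3 fell (8 adjusted over the list alone): the actin-nucleating LMOD1 (-1.54 ± 0.31), RGS5 (-1.32 ± 0.27) and the myosin gene MYH11 (-1.22 ± 0.26). For each of these last lists adjusted p = 0.181 with an estimated correlation. Of 20 activated fibroblast genes COL10A1, a collagen gene (1.30 ± 0.29), and CTHRC1, a secreted collagen-associated gene (2.71 ± 0.74), rose, and no more did so adjusted over the list alone (adjusted p = 0.66 with an estimated correlation). In AIS replicate 2 the scores of endothelial (8.38), resident fibroblast (9.31) and smooth muscle markers (9.45) lay above those of the other 5 AIS libraries. Without that library 22 endothelial, 8 resident fibroblast and 7 smooth muscle markers fell. Without 1 patient the endothelial count ran from 12 (patient 5) to 22 (patient 2), the resident fibroblast count from 2 (patient 5) to 9 (patient 2) and the smooth muscle count from 1 (patient 3) to 7 (patient 2). RGS5 and MYH11 lost the threshold without patient 3 (adjusted p up to 0.0633 and 0.0548), RGS5 also without patient 5 and MYH11 also without patient 1. GPIHBP1 lost it without each patient but 2 (0.102), in edgeR and without the patient block. COL10A1 lost it without patients 3 and 5 (0.0801), and CTHRC1 without patients 1, 3, 5 and 6 (0.163), in edgeR, in the FPKM table and without a filter or a trend.

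Of 19 alveolar type 1 markers 5 fell (9 adjusted over the list alone): AGER, CAV1, the caveolin that coats membrane pits (-1.82 ± 0.32), SPOCK2 (-1.59 ± 0.35), CLIC5 (-1.07) and ANXA3 (-0.89). HOPX, a transcriptional regulator, rose by 1.82. The list had a median of -0.89 and adjusted p = 0.191 with an estimated correlation. The number of falls ran from 2 without patient 1 to 9 without patient 2, and was 9 without AIS replicate 2, whose type 1 score of 9.65 lay above the 8.24 to 8.95 of the other AIS libraries. HOPX lost the threshold without patients 1, 3, 4 and 5 (adjusted p up to 0.0766), SPOCK2 without patients 1, 3 and 5 (0.0926), CLIC5 without patients 1, 3, 5 and 6 (0.0948) and ANXA3 without each patient but 2 (0.15). HOPX, SPOCK2 and CLIC5 were also lost without a trend, HOPX, SPOCK2 and ANXA3 without the patient block, and ANXA3 in edgeR. Of 9 club and goblet cell markers SCGB1A1, the main secreted protein of club cells, fell by 2.73 ± 0.77 (adjusted p = 0.047), and it was the single call adjusted over the list alone. It passed the threshold when patient 4 was left out and with no other patient left out (adjusted p up to 0.167), and it was lost with a pseudocount of 0.5, library weights, no filter, no trend and the FPKM table. In limma 0 of 9 ciliated cell markers passed, against 4 at an unadjusted p, 0 in edgeR and 2 in DESeq2. Adjusted over the list alone 4 passed, the dynein genes DNAH9 (-2.05), DNAI1 (-2.08) and DNAH5 (1.61), and SNTN (-1.82).

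Of 11 neutrophil markers 2 fell (7 adjusted over the list alone), the calcium-binding genes S100A8 (-2.68 ± 0.61) and S100A12 (-2.97 ± 0.84), with adjusted p = 0.191 with an estimated correlation. FABP4, a fatty acid binding protein of lung macrophages and capillaries, fell by 2.83 ± 0.64 and was the single call among 19 macrophage markers, also adjusted over the list alone. IL7R, the interleukin 7 receptor, fell by 1.37 ± 0.25 (adjusted p = 0.00493) and was the single call among 19 T cell markers on both scales, with adjusted p = 0.594 with an estimated correlation. Among B cell markers 0 of 9 passed in limma, edgeR and DESeq2 or adjusted over the list alone, and 1 passed at an unadjusted p (adjusted p = 0.53 with an estimated correlation). Of the 8 plasma cell markers and the 21 interferon response genes 0 passed in limma, edgeR or DESeq2, adjusted over the list alone or at an unadjusted p, with medians of 0.49 and -0.02. Of 9 mast cell markers 0 passed in limma and edgeR, 3 in DESeq2 and 4 at an unadjusted p, and 3 passed adjusted over the list alone: GATA2 (-1.25), SLC18A2 (-1.02) and MS4A2 (-1.11). For that list adjusted p = 0.524 with an estimated correlation. HLA-E, an inhibitory ligand of natural killer cells, fell by 1.30 ± 0.21 (adjusted p = 0.00245) as the single call among 22 antigen presentation genes (5 adjusted over the list alone; adjusted p = 0.585 with an estimated correlation). Of 3 red blood cell genes the beta globin gene HBB fell by 2.77 ± 0.51 and CA1, a carbonic anhydrase gene, rose by 1.80 ± 0.49. Adjusted over the list alone HBA2 (-1.65) passed too. AIS replicate 2 had the highest neutrophil (7.44) and red blood cell (7.49) scores and the lowest T cell score (3.26) of the AIS libraries. Without it 6 neutrophil markers and 5 antigen presentation genes fell. S100A8 lost the threshold without patients 3 and 5 (adjusted p up to 0.0952), FABP4 without patients 1, 3 and 5 (0.0936), S100A12 without each patient but 2 (0.151) and CA1 without each patient but 6 (0.17). S100A12 and CA1 were also lost in edgeR, S100A12 after quantile and TMM scaling, and CA1 without AIS replicate 2, after the removal of GC content and length trends, with library weights and without a filter or a trend.

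Of 20 immediate early genes, which are induced within minutes of a stimulus, 8 fell (17 adjusted over the list alone), including the transcription factor genes JUN (-1.29 ± 0.23) and FOSB (-2.15 ± 0.42), with a list median of -1.12 and adjusted p = 0.181 with an estimated correlation. Of 36 cell cycle genes 3 rose (6 adjusted over the list alone): MKI67, a marker of dividing cells (1.55 ± 0.36), MCM4, part of the replication helicase (1.90 ± 0.49), and the centromere gene CENPF (1.31 ± 0.35), with adjusted p = 0.289 with an estimated correlation. HSPA5, the main chaperone of the endoplasmic reticulum, rose by 1.13 ± 0.20 (adjusted p = 0.0043), the single call among 17 genes of endoplasmic reticulum stress (2 adjusted over the list alone, PDIA4 being the other; adjusted p = 0.53 with an estimated correlation). Of 19 NRF2 targets ME1 (1.31 ± 0.33) and the quinone reductase gene NQO1 (1.84 ± 0.51) rose (5 adjusted over the list alone), with adjusted p = 0.524 with an estimated correlation. RPLP0 (1.15 ± 0.24) rose as the single call among 57 ribosomal protein genes, also adjusted over the list alone. Of 36 oxidative phosphorylation genes 0 passed in limma and edgeR or adjusted over the list alone, 2 in DESeq2 and 5 at an unadjusted p. For each of the last pair of lists adjusted p = 0.53 with an estimated correlation. The cell cycle count ran from 0 without patient 1 to 9 without patient 2, and was 7 without AIS replicate 2, whose cell cycle score of 2.30 lay below the 5.28 to 6.01 of the others. The immediate early count ran from 4 (without patient 1) to 11 (without patient 4), and the ribosomal count was 8 without patient 2. MKI67 lost the threshold without patients 1, 3 and 6 (adjusted p up to 0.0952), MCM4 and CENPF without patients 1, 3, 4 and 5 (0.103 and 0.157), ME1 without patients 1, 3, 5 and 6 (0.109), NQO1 without patients 1, 4, 5 and 6 (0.164) and RPLP0 without patients 1 and 3 (0.0551). MKI67, CENPF and NQO1 were also lost in the FPKM table, MCM4, CENPF and NQO1 without a filter and with 2 groups only, CENPF in edgeR and NQO1 without AIS replicate 2.

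Of 11 regulators of epithelial-mesenchymal transition, a shift of epithelial cells towards a migratory state, ZEB1 (-1.29 ± 0.20), ZEB2 (-1.04 ± 0.24) and TCF4 (-0.94) fell and the integrin gene ITGB6 rose (1.48 ± 0.35). Adjusted over the list alone 5 fell and 1 rose (adjusted p = 0.289 with an estimated correlation). Endothelial (-2.08), smooth muscle (-1.08) and resident fibroblast (-0.99) scores also fell in AIS, and the epithelial score rose (1.05). A change within epithelial cells is therefore not shown by these genes. TIMP3, an inhibitor of metalloproteases, fell by 1.80 ± 0.33 as the single call among 18 proteases and regulators, and MMP13 (3.01) passed with it adjusted over the list alone. MXI1 (-0.996 ± 0.27) fell as the single call among 20 hypoxia genes, and 4 passed adjusted over the list alone. Of 12 histone genes 0 passed in limma, edgeR and DESeq2 or adjusted over the list alone, and 1 passed at an unadjusted p, with a median of -0.10, a mean of 0.00 and a test direction of lower. In the panel of 25 long noncoding RNAs PVT1, which lies beside MYC, rose by 2.53 ± 0.61 and LINC00312 fell by 1.45 ± 0.40, and adjusted over the list alone LINC00472 (-1.63) passed too. ZEB2 and TCF4 lost the threshold without patients 1, 3 and 5 (adjusted p up to 0.105 and 0.132), ITGB6 without each patient but 2 (0.1), MXI1 without each patient but 4 (0.157), PVT1 without patients 1, 3 and 5 (0.117) and LINC00312 without patients 1, 3, 5 and 6 (0.179). MXI1 and LINC00312 were also lost without a filter or a trend, and MXI1 and PVT1 with 2 groups only.

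**Figure D2:**
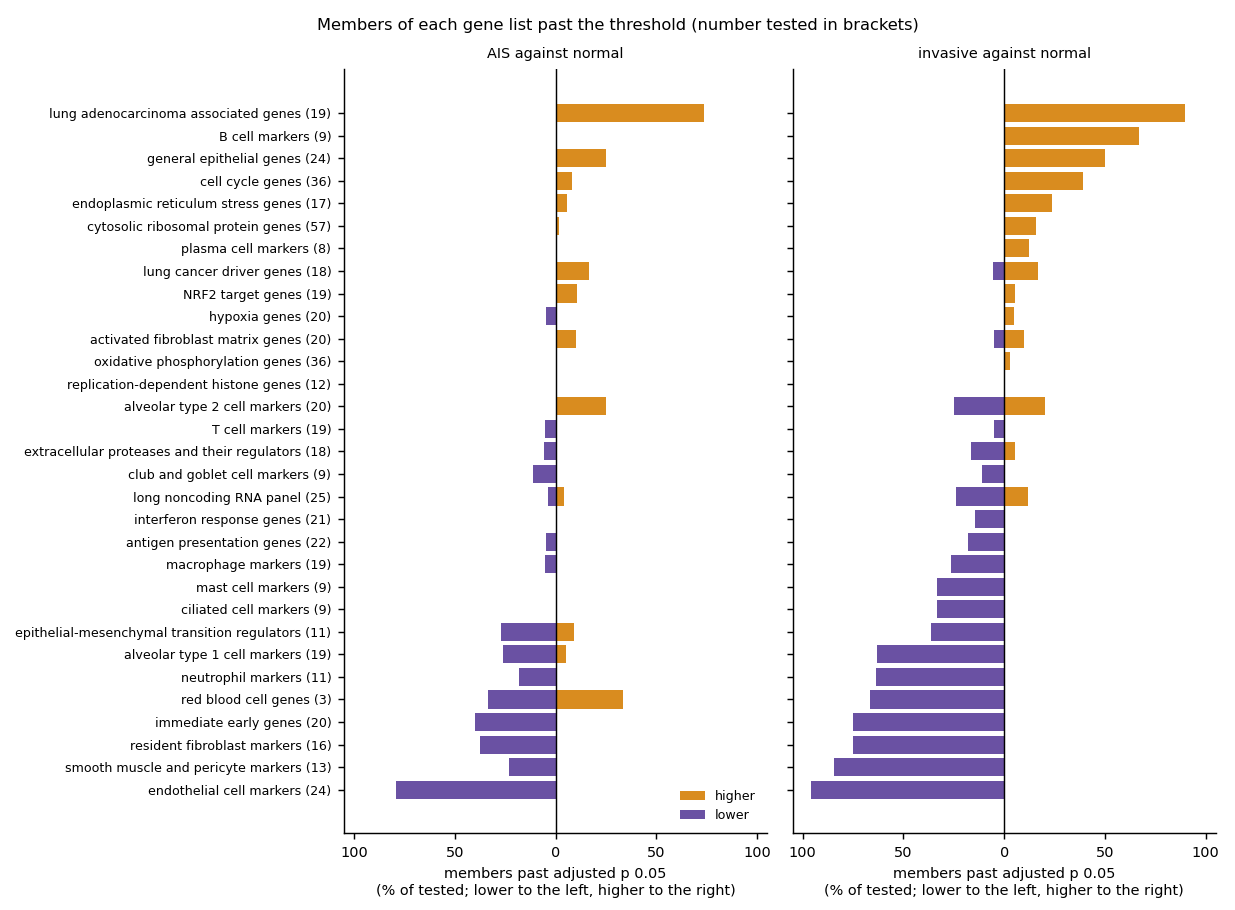
Members of each gene list past the limma threshold as a percentage of those tested (numbers in brackets), higher members as orange bars to the right and lower members as purple bars to the left, for AIS (left panel) and invasive tissue (right panel) against normal lung. Of 24 endothelial markers 19 and 23 were lower, and of 19 adenocarcinoma associated genes 14 and 17 were higher.

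The comparison of invasive adenocarcinoma with normal lung asks what distinguishes the invading tumour from histologically normal lung of the same patients. CEACAM5 rose by 7.11 ± 0.82 (adjusted p = 3.61e-05), to a mean normalized count of 10089 ± 7788 (SD, n = 6). SLC6A4, the serotonin transporter gene of lung endothelium, fell by 6.88 ± 0.71 (adjusted p = 1.33e-05) to 15.2 ± 18.5, and AGER fell by 4.71 ± 0.35 (adjusted p = 7.78e-07) to 644 ± 413. CR2, a complement receptor of B cells and follicular dendritic cells, rose by 4.14 ± 0.92 (adjusted p = 0.00636), from 9.22 ± 14.7 to 178 ± 217. Each of these genes moved the same way in 6 of 6 patients. In limma 1924 of 14758 genes passed, 573 higher and 1351 lower (29.8% higher), with 3946 at an unadjusted p under 0.05. The share of higher calls was 41.9% after quantile normalization and 41.8% in DESeq2, and the median of all genes was -0.04 (0.06 after quantile normalization). Without the patient block 854 genes passed, and without patient 3 or patient 5 the number was 1134 or 1235.

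Of the 20 genes named by the rule all passed the threshold without any 1 patient and under each alternative tried. Of 77 called members named over the lists 55 passed without any 1 patient and 46 under every alternative, while 28 were lost without the patient block, 14 without a trend, 14 with 2 groups only and 10 in edgeR. After CEACAM5, the highest rises were those of GCNT3 (5.56 ± 0.92), XDH (5.46 ± 0.83), the heparan sulfate sulfotransferase gene HS6ST2 (5.36 ± 0.84), the metalloprotease gene MMP7 (4.64 ± 1.03), TOX3 (4.58 ± 0.78), the serine protease gene TMPRSS4 (4.48 ± 0.88) and GYG2 (4.47 ± 0.65). SPINK1, a trypsin inhibitor gene, rose by 4.56 ± 1.01, with 506 reads in invasive tissue and 3 in normal lung, a ratio of normalized means of 162 (95% counting interval 55.1 to 788). DSPP, a gene of tooth matrix, rose by 4.55 ± 0.92, with 436 reads and 3 reads. ANKRD1, a gene responsive to mechanical strain, fell by 7.45 ± 0.85 (adjusted p = 3.38e-05), from 1766 ± 2013 to 11.8 ± 16.01 normalized counts. TMEM100, an endothelial gene downstream of bone morphogenetic protein receptors, fell by 5.59 ± 0.53, and SEMA3G, an endothelial semaphorin gene, fell by 5.02 ± 0.47 (adjusted p = 6.93e-06 each). FCN3, which starts the lectin pathway of complement, fell by 5.52 ± 0.82, COLEC10 fell by 5.60 ± 0.74, the sodium-glucose transporter gene SLC5A1 by 5.48 ± 0.64, FABP4 by 4.90 ± 0.64 and TCEAL2 by 4.81 ± 0.56. BTNL8 had 406 reads in normal lung and 0 in invasive tissue, a level at least 131-fold lower, with the caution on BTNL3 given above.

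In invasive tissue 17 of 19 adenocarcinoma associated genes rose over normal lung (18 adjusted over the list alone), with a median of 3.55, among them ABCC3 (2.89 ± 0.20, adjusted p = 6.95e-07), CEACAM6 (2.75 ± 0.27) and HMGB3, a chromatin protein gene (3.64 ± 0.40). For this list adjusted p = 0.0506 with an estimated correlation, and fry gave an adjusted p of 8.5e-05. Of 24 epithelial genes 12 rose (18 adjusted over the list alone), for example EPCAM (2.25 ± 0.30), CLDN4 (1.90 ± 0.30) and ESRP1 (1.98 ± 0.31), with adjusted p = 0.0862 with an estimated correlation. Alveolar type 2 markers split. LPCAT1 (1.74 ± 0.36), NKX2-1 (1.60 ± 0.36), SLC34A2 (1.65) and NAPSA (1.52) rose, while HHIP, a hedgehog-binding protein gene (-2.70 ± 0.56), LAMP3 (-1.32) and the surfactant protein genes SFTPC (-3.58 ± 0.91), SFTPA1 (-1.89 ± 0.57) and SFTPA2 (-1.96 ± 0.55) fell, each in 5 of 6 patients. SFTPC varied widely, with means of 1729 ± 572 normalized counts in normal lung (935 to 2503) and 1095 ± 2379 in invasive tissue (1.33 to 5949, SD, n = 6 each), so that the highest invasive library lay above every normal one. Adjusted over the list alone 6 of the 20 rose and 5 fell, with a median of -0.17, a mean of -0.23 and a list test in the direction of higher that did not pass. Of 18 driver genes 3 rose, among them ERBB2 (1.19 ± 0.26) and SMARCA4 (0.59), and 1 fell, with the same counts adjusted over the list alone. Without patients 3 or 6 1 driver rose, and without patients 2, 4 or 5 0 fell over all genes in limma. The epithelial count ran from 7 (without patient 1) to 14 (without patient 2), and the type 2 falls were 3 without patient 4, 2 without patients 5 or 6, 2 in edgeR, 4 in DESeq2 and 1 without the patient block. SFTPC lost the threshold without patient 3 (adjusted p = 0.0519), LAMP3 without patients 4 to 6 (0.0841), SFTPA1 without patients 1, 4, 5 and 6 (0.13) and SFTPA2 without patients 2, 5 and 6 (0.0959). All 4 were lost without a trend or the patient block, the latter 3 also in edgeR, without a filter and with library weights, and SFTPA1 in DESeq2. NAPSA was lost without patient 3 (0.0605), and SMARCA4 without each patient but 2 (0.146), in the FPKM table and without a trend or the block.

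Of 24 endothelial markers 23 fell (24 adjusted over the list alone), with a median of -2.99. CDH5 fell by 3.51 ± 0.30 (adjusted p = 4.57e-06) and TEK by 3.20 ± 0.29 (adjusted p = 5.53e-06). For this list adjusted p = 0.0506 with an estimated correlation, and fry gave an adjusted p of 5.25e-05. Of 19 type 1 markers 12 fell (15 adjusted over the list alone), including CLIC5 (-2.43 ± 0.25) and CAV1 (-3.02 ± 0.32), while 1 was higher at an unadjusted p. Of 16 resident fibroblast markers 12 fell (14 adjusted over the list alone), with ADH1B at -2.11 ± 0.28 and the methyltransferase gene INMT at -2.37 ± 0.35. Of 13 smooth muscle and pericyte markers 11 fell (12 adjusted over the list alone), such as LMOD1 (-2.13 ± 0.31) and MYH11 (-1.63 ± 0.26). For each of these 3 lists adjusted p = 0.0862 with an estimated correlation. COL10A1 (1.54 ± 0.29) and CTHRC1 (2.37 ± 0.74) rose and COL12A1 (-1.33 ± 0.41) fell among 20 activated fibroblast genes, with the same counts adjusted over the list alone. Of 9 ciliated cell markers DNAI1 (-3.70 ± 0.79), DNAH9 (-3.28 ± 0.77) and RSPH1 (-2.97 ± 0.92) fell (5 adjusted over the list alone, adjusted p = 0.4 with an estimated correlation), while 1 was higher at an unadjusted p. SCGB1A1 fell by 4.31 ± 0.77 as the single call among 9 club and goblet cell markers, and adjusted over the list alone PIGR (2.23) and CYP2F1 (-2.02) passed too. Without 1 patient the endothelial count lay between 20 and 23, the type 1 count between 11 and 12, the resident fibroblast count between 8 and 12 and the smooth muscle count between 9 and 11. RSPH1 lost the threshold without patients 1, 3, 4 and 5 (adjusted p up to 0.141), COL12A1 without each patient but 6 (0.173) and CTHRC1 without patients 1, 3, 5 and 6 (0.179). All 3 were also lost in edgeR, without a filter or a trend and with 2 groups only, RSPH1 in DESeq2 and with library weights, and COL12A1 and CTHRC1 in the FPKM table and after the removal of GC content and length trends. Among activated fibroblast genes the falls ran from 0 (without patient 1) to 4 (without patient 6) and the rises from 1 (without patient 3) to 3 (without patient 4), with 1 rise and 0 falls in edgeR, 5 and 1 in DESeq2 and 6 and 3 at an unadjusted p in limma.

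Of 9 B cell markers 6 rose, also adjusted over the list alone, such as CR2, the transcription coactivator gene POU2AF1 (2.92 ± 0.79), MS4A1 (2.60) and PAX5 (2.72), with adjusted p = 0.2 with an estimated correlation. SLAMF7 (1.67 ± 0.54) rose as the single call among 8 plasma cell markers, with FCRL5 (2.68) beside it adjusted over the list alone (adjusted p = 0.391 with an estimated correlation). IL7R fell by 1.23 ± 0.25 as the single call among 19 T cell markers on both scales, in a list with a median of 0.17. Patient by patient, the B cell score changed by 2.32 ± 1.35 more than the T cell score and the T cell score by 3.11 ± 1.64 more than the endothelial score (SD, n = 6, 6 of 6 patients each, exact sign flip test, two-sided p = 0.03125, the smallest p possible, and 0.0417 adjusted over 8 such comparisons). These comparisons between lists were chosen after the scores were seen, and they share lists, so they are not independent. By itself the B cell score was higher in 5 of 6 patients, which did not pass (exact p = 0.0625, adjusted p = 0.121), and 0 of 31 list scores passed that exact test after adjustment in any of the comparisons (lowest adjusted p = 0.0881, in invasive against normal tissue, where 7 scores were lower and 4 higher in 6 of 6 patients). With 6 patients no exact p can lie under 0.03125, so a pass over 31 lists needs many of them at that value together. The 0 therefore decides little. Of 11 neutrophil markers 7 fell (10 adjusted over the list alone), led by the receptor gene FCGR3B (-4.30 ± 0.68), S100A8 (-3.32 ± 0.61) and the channel gene AQP9 (-3.53 ± 0.66), with adjusted p = 0.0862 with an estimated correlation. Among 19 macrophage markers FABP4, the scavenger receptor gene MARCO (-2.71 ± 0.52), ALOX5 (-1.04 ± 0.30), VSIG4 (-1.23) and PPARG (-0.97) fell (6 adjusted over the list alone; adjusted p = 0.438 with an estimated correlation). Of 9 mast cell markers GATA2 (-1.999 ± 0.39), the histamine-synthesizing HDC (-1.44 ± 0.36) and SLC18A2 (-1.23 ± 0.35) fell (5 adjusted over the list alone; adjusted p = 0.274 with an estimated correlation). HBB fell by 4.28 ± 0.51 and HBA2 by 4.19 ± 0.72 among 3 red blood cell genes, also adjusted over the list alone. The B cell count was 1 without patient 5 and 7 without patient 4. CR2 held without any 1 patient. MS4A1 lost the threshold without each patient but 4 (adjusted p up to 0.155) and PAX5 without patients 1, 3, 5 and 6 (0.174), both without the patient block and with 2 groups only. POU2AF1 lost the threshold without patients 1, 2 and 5 (adjusted p up to 0.105) and SLAMF7 without each patient but 4 (0.15), without whom 4 plasma cell markers rose, against 0 without patient 1. POU2AF1, SLAMF7, ALOX5 and SLC18A2 were also lost in edgeR and with 2 groups only, ALOX5 with TMM rescaling and SLAMF7 after the removal of GC content and length trends, and edgeR called 0 plasma cell markers, against 3 in DESeq2 and 2 at an unadjusted p in limma. The macrophage count was 2 without patient 1, and ALOX5 lost the threshold without patients 1, 3, 4 and 5 (0.115), VSIG4 without patients 1, 3, 4 and 6 (0.18), PPARG without each patient but 2 (0.152), HDC without patient 3 (0.0575) and SLC18A2 without patients 1, 3 and 5 (0.102). VSIG4 and PPARG were also lost in edgeR and after quantile and TMM scaling.

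Of 36 cell cycle genes 14 rose (19 adjusted over the list alone), including MKI67 (2.10 ± 0.36), CENPF (1.96 ± 0.35) and the topoisomerase gene TOP2A (2.45 ± 0.46), with a list median of 1.76 and adjusted p = 0.0862 with an estimated correlation. Of 20 immediate early genes 15 fell (17 adjusted over the list alone), such as the phosphatase gene DUSP1 (-1.83 ± 0.26), JUN (-1.63 ± 0.23) and KLF6 (-1.44 ± 0.21), again with adjusted p = 0.0862 with an estimated correlation. In the list of endoplasmic reticulum stress HSPA5 (1.37 ± 0.20), the disulfide isomerase gene PDIA4 (1.52 ± 0.30), HYOU1 (0.94 ± 0.24) and the secretory regulator gene XBP1 (1.15) rose among 17 members (6 adjusted over the list alone; adjusted p = 0.262 with an estimated correlation). Of 57 ribosomal protein genes 9 rose, also adjusted over the list alone, among them RPLP0 (1.20 ± 0.24), RPS2 (1.11 ± 0.27) and RPS18 (0.94 ± 0.25), with adjusted p = 0.321 with an estimated correlation. NQO1 (1.62 ± 0.51) among 19 NRF2 targets and SDHC (0.80 ± 0.25) among 36 oxidative phosphorylation genes rose, each as a single call. Adjusted over the list alone 0 passed in limma, with 5 members of each list at an unadjusted p and, over all genes, 1 of each in edgeR and 3 and 1 in DESeq2. For these lists adjusted p = 0.438 and 0.432 with an estimated correlation. The cell cycle count ran from 6 (without patient 5) to 13 (without patient 2), the ribosomal count from 1 (patient 3) to 13 (patient 2) and the immediate early count from 12 to 16. Without the patient block the cell cycle count was 3 and the ribosomal count 0, against 19 and 21 in DESeq2. The count of stress genes was 2 without patient 1 and 2 without the patient block. HYOU1 lost the threshold without patient 1 (adjusted p = 0.0671), XBP1 without patients 1, 3 and 5 (up to 0.131) and without a filter or a trend, RPS2 without patient 3 (0.0576), RPS18 without patients 1, 3 and 4 (up to 0.0739), NQO1 without patients 1, 4, 5 and 6 (up to 0.167) and SDHC without each patient but 5 (up to 0.167). NQO1 and SDHC were also lost without a filter or a trend, with 2 groups only and after the removal of GC content and length trends, and NQO1 in the FPKM table.

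In the list of epithelial-mesenchymal transition ZEB1 (-1.46 ± 0.20), ZEB2 (-1.27 ± 0.24), TCF4 (-1.11 ± 0.23) and VIM (-0.81) fell, also adjusted over the list alone (adjusted p = 0.2 with an estimated correlation). In the same tissue endothelial (-3.06), smooth muscle (-1.75) and resident fibroblast (-1.58) scores fell and the epithelial score rose (1.23). The falls cannot be told apart from a lower share of such cells, and a change within epithelial cells is not shown. Among 18 proteases and regulators ADAM28, a membrane protease gene (1.97 ± 0.32), rose, and 3 fell, such as TIMP3 (-2.57 ± 0.33) and TIMP2 (-0.83), with the same counts adjusted over the list alone. RSAD2 (-1.33 ± 0.29), IFIT2 (-1.51 ± 0.39) and IFIT3 (-1.34 ± 0.35) fell among 21 interferon response genes, also adjusted over the list alone (adjusted p = 0.572 with an estimated correlation). HLA-E (-1.61 ± 0.21), HLA-C (-0.61 ± 0.18), B2M (-0.82 ± 0.25) and NLRC5 (-1.05) fell among 22 antigen presentation genes (5 adjusted over the list alone, TAP2 being the other). ENO1 (1.22 ± 0.35) rose as the single call among 20 hypoxia genes, with 0 adjusted over the list alone (5 at an unadjusted p, 1 in edgeR and 3 in DESeq2 over all genes), a median of 0.06, a mean of -0.19 and a test direction of lower. Of 12 histone genes 0 passed in limma, edgeR and DESeq2 or adjusted over the list alone, and 1 at an unadjusted p. In the long noncoding RNA panel PVT1 (3.12 ± 0.61), AFAP1-AS1 (2.06) and KCNQ1OT1 (0.46) rose and 6 of 25 fell, such as LINC00312 (-2.14 ± 0.40) and LINC00472 (-2.57 ± 0.51), with the same counts adjusted over the list alone, a median of 0.26, a mean of -0.01 and a test direction of higher. IFIT2 lost the threshold without patient 1 (adjusted p = 0.083), IFIT3 without patients 1, 2 and 6 (0.0838), HLA-C without each patient but 2 (0.16), B2M without patients 1, 3, 4 and 5 (0.128) and ENO1 without patients 1, 4, 5 and 6 (0.106). HLA-C and B2M were also lost after quantile and TMM scaling, in the FPKM table, without a trend, with the patient as a random effect and in edgeR, which called 1 antigen presentation gene, as limma did without patient 1. HLA-C was also lost with 2 groups only and after the removal of GC content and length trends, and B2M without a filter. NLRC5 was lost without each patient but 5 (0.176), in edgeR, after quantile and TMM scaling and in the FPKM table. Of the 3 falls among proteases and regulators 1 was left without patients 3 or 5, in edgeR and without the patient block, and TIMP2 was lost without patients 1, 3, 4 and 5 (0.138), in edgeR and after quantile scaling. The falls in the long noncoding RNA panel numbered 3 without patients 1 or 5 and 2 without patients 3 or 4, and its rises 1 without patients 1 or 3, as AFAP1-AS1 was lost without patients 1 and 3 (0.0983) and KCNQ1OT1 without any 1 of the 6 patients (0.148).

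**Figure D3:**
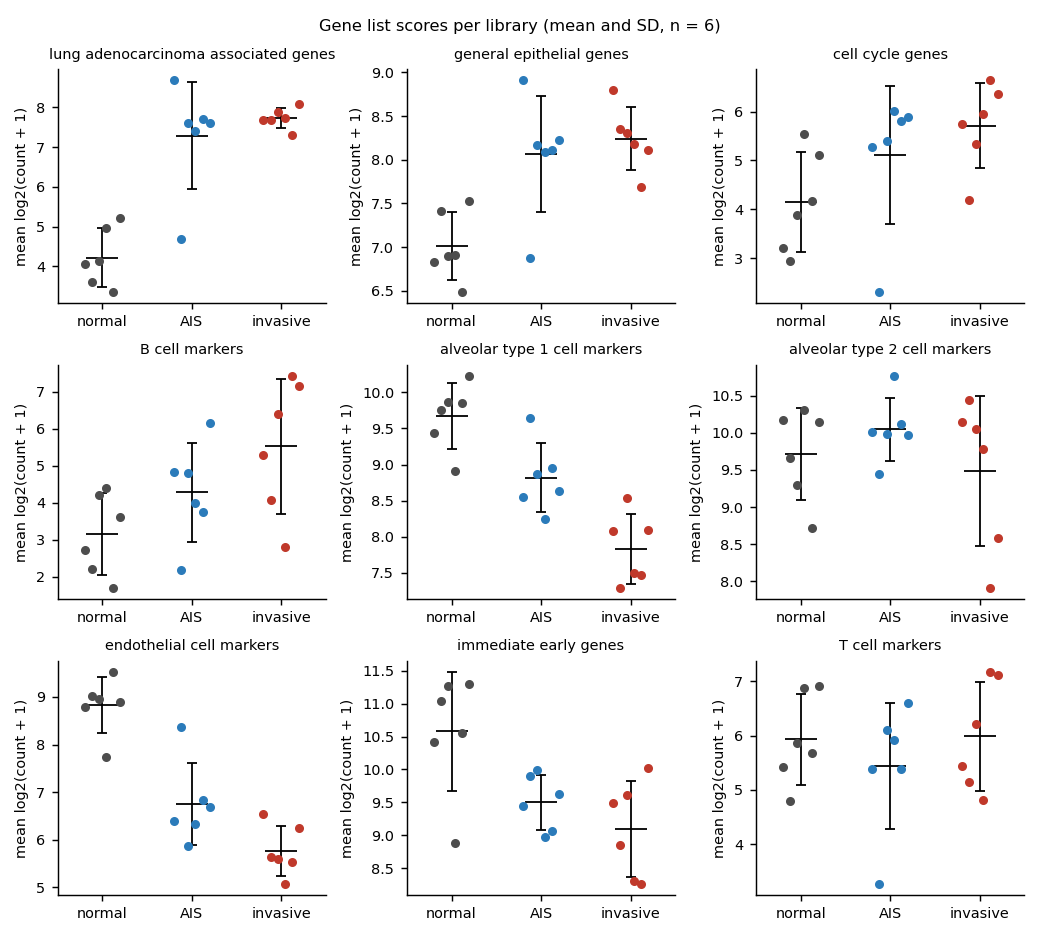
Scores of 9 gene lists, the mean log2(normalized count + 1) over each list's members, per library (points) in each tissue type, with the group mean and SD (n = 6). Endothelial scores averaged 8.82 in normal lung, 6.75 in AIS and 5.77 in invasive tissue, and AIS replicate 2 is the AIS point at 8.38.

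Invasive adenocarcinoma against AIS of the same patients addresses what separates an invading from a noninvasive lesion. AGER was lower in invasive tissue in 6 of 6 patients, with a log2 difference of -2.15 ± 0.35 that did not pass the threshold (adjusted p = 0.132). CLIC5, a chloride channel gene of type 1 cells, differed by -1.36 ± 0.25 (6 of 6 patients, adjusted p = 0.279) and ANKRD1 by -4.31 ± 0.85 (5 of 6, adjusted p = 0.426). In the other direction ADAM28 differed by 1.48 ± 0.32 (6 of 6, adjusted p = 0.559), SOWAHB by 2.85 ± 0.77 (6 of 6, 0.922) and SKIDA1 by 2.39 ± 0.69 (5 of 6, 0.97). In limma 0 of 14758 genes passed, with 667 (4.52%) at an unadjusted p under 0.05. The count was 0 in edgeR and 11 in DESeq2: ADAM28 higher, and AGER, ANKRD1, CLIC5, HDC, LOC349160, LPHN3, OR5E1P, SEMA3G, SLC19A3, TMEM100 lower. DESeq2 fitted LOC349160 at -21.4, against -2.06 for AGER, and a value of that size is not read as a measured change. With the patient as a random effect AGER and CLIC5 passed (adjusted p = 0.0401 each), and without patient 3 AGER did (adjusted p = 0.0259).

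By list, 0 members passed over all genes in any of the lists. Of 19 type 1 markers 9 fell adjusted over the list alone, with a median of -0.99 and adjusted p = 0.112 with an estimated correlation. At an unadjusted p 11 were lower, with 0 called in edgeR and 2 in DESeq2. Of 24 endothelial markers 10 fell adjusted over the list alone, with a median of -0.76, 12 at an unadjusted p, 0 in edgeR, 1 in DESeq2 and adjusted p = 0.323 with an estimated correlation. Adjusted over the list alone the neutrophil genes CSF3R (-1.33) and FCGR3B (-1.99), the mast cell gene HDC (-1.63 ± 0.36), the globin genes HBA2 (-2.54) and HBB (-1.52), and ADAM28 passed as well. Camera at the preset correlation passed 20 of 30 lists, 9 higher, such as cell cycle genes (median 0.67) and B cell markers (median 1.20), and 11 lower, while 0 passed with an estimated correlation and 0 in fry. For cell cycle, B cell and neutrophil lists adjusted p = 0.352 with an estimated correlation. Median, mean and test direction differed in sign for NRF2 targets (-0.10, -0.12, higher), antigen presentation (-0.02, -0.04, higher) and the long noncoding RNA panel (-0.03, -0.06, higher).

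Genes called in AIS were largely called in invasive tissue too. Of 281 genes higher in AIS 230 were higher in invasive tissue (10.9 expected for independent lists), and of 470 lower genes 449 were lower (43.0 expected). All of them had the same sign. Both comparisons share the normal libraries, which alone gave a correlation of 0.496 between the log2 changes of unchanged simulated groups with independent libraries, against 0.853 observed. AIS and invasive libraries of a patient also deviated together, and with each patient's deviations kept together, in 31 exchanges of their signs, the correlation with no change had a median of 0.591 (0.385 to 0.698). The covariance was 0.719, against 0.135 with independent libraries and a median of 0.170 (0.0775 to 0.236) with the patients kept together, a difference of 0.549 from the latter. With different patients on each side the correlation had a median of 0.479 (0.375 to 0.607 over 20 splits), and the covariance a median of 0.547. For 300 genes chosen in 3 patients and measured in the other 3, the AIS change was a median of 88.3% of the invasive change for risen genes (48.8% to 125% over 20 splits, above the invasive change in 8) and 71.9% for fallen genes (53.0% to 90.2%). No gene passed the threshold in order from normal over AIS to invasive tissue in limma (0, against 7 in DESeq2). Such an order needs a call between AIS and invasive tissue, of which limma made 0. The ordered 0 was therefore fixed and says nothing further about stepwise change.

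**Figure D4:**
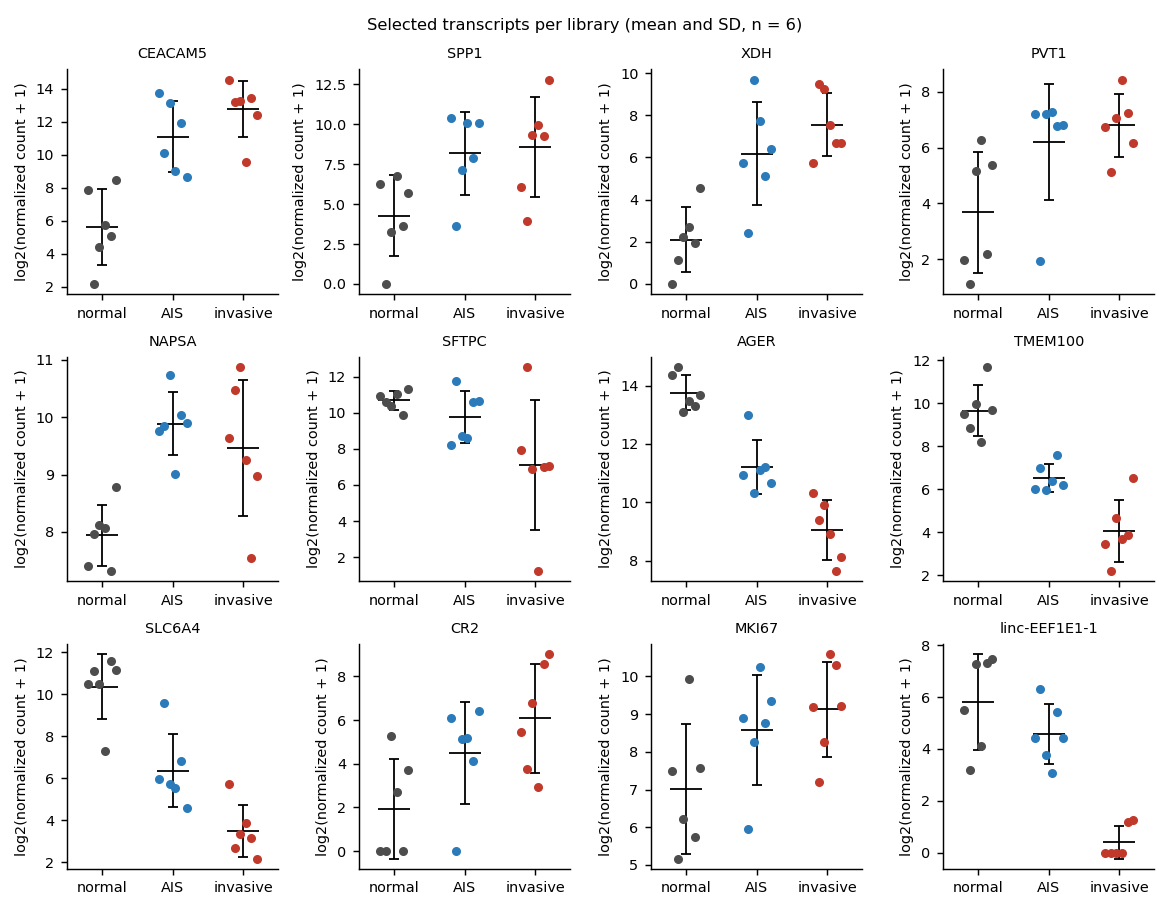
Normalized count of 12 transcripts as log2(count + 1) per library (points) in each tissue type, with the mean and SD (n = 6). AGER averages 14949 counts in normal lung, 2907 in AIS and 644 in invasive tissue, and linc-EEF1E1-1 92.7, 30.0 and 0.448.

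Among lincRNAs, fewer passed the threshold between AIS and normal lung than between invasive tissue and normal lung, a difference that was not tested. In AIS linc-DUSP10-1 rose by 3.59 ± 0.76 (adjusted p = 0.0196), linc-MRPL33-1 by 3.34 ± 0.57 (0.00563) and linc-GRIP1-1 by 2.42 ± 0.54 (0.0255), each higher in 6 of 6 patients. In 5 of 6 patients linc-COX4NB-9 (-2.74 ± 0.50) and linc-COX4NB-8 (-3.27 ± 0.70) were lower. The last of the 6 calls among 1070 lincRNAs, linc-CBR1-2 (3.71), was chosen after its value was seen. Next among the lower ones, linc-TACC3-1 did not pass (-2.50 ± 0.62, adjusted p = 0.0677). In invasive tissue 79 passed, 27 higher and 52 lower. The highest rises were those of linc-DUSP10-1 (4.13 ± 0.76), linc-LRRC49-4 (3.97 ± 0.97), linc-CBR1-2 (3.89 ± 0.79), linc-MRPL33-1 (3.67 ± 0.57) and linc-PIK3C2G-2 (3.54 ± 1.06). The strongest falls were those of linc-EEF1E1-1 (-5.40 ± 0.79), linc-COX4NB-8 (-5.06 ± 0.70), linc-HIST3H2A-2 (-4.61 ± 0.87), linc-COX4NB-9 (-4.60 ± 0.50, adjusted p = 2.98e-06) and linc-EIF3F-1, which had 2 reads in invasive tissue and 152 in normal lung (ratio of normalized means 79.1, 95% counting interval 21.5 to 659). Against AIS, 1 lincRNA passed in limma: linc-EEF1E1-1 fell by 4.15 ± 0.79 (adjusted p = 0.0245, lower in 6 of 6 patients), with 4 reads in invasive tissue and 178 in AIS. It passed when patient 2 was left out and with no other patient left out (adjusted p up to 0.275). The highest values in the other direction, linc-FAIM3-1 (2.49), linc-HIST1H2AI-1 (2.29) and linc-MAN1A1-1 (2.22), did not pass. The AIS count was 37 without patient 2, 38 without AIS replicate 2, 48 in DESeq2, 32 after quantile normalization, 3 without patient 5, 2 without patient 3, 1 without patient 6 and 0 without patient 1, and each of the 5 lincRNAs named first was lost without patient 1 (adjusted p between 0.14 and 0.207 at the most). The invasive count was 46 without patient 3 and 42 without patient 5. There linc-LRRC49-4 lost the threshold without patients 1, 2 and 5 (adjusted p up to 0.0966), linc-PIK3C2G-2 without patients 1, 3, 5 and 6 (0.214) and linc-EIF3F-1 without patient 3 (0.0505). The first pair was also lost in edgeR and without a filter, and the last in the FPKM table. Of the 6 AIS calls all 4 higher and both lower ones were called the same way in invasive tissue. Some lincRNAs named here followed a gene (correlation above 0.99) and are not separate from the gene results. They were linc-COX4NB-9 (FOXF1-AS1), linc-CBR1-2 (LOC100506385), linc-LRRC49-4 (LOC145837) and linc-MAN1A1-1 (LOC285762).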

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

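The test of sequencing depth for AIS replicate 2 and the tests of GC content and of single patients for the B cell markers were chosen before their results were seen, while the other tests of this part, the counts of exchanged libraries and the fits without AIS replicate 2 were chosen afterwards. Over 174 groups of 6 libraries, 22 values lay far from the rest by a test of the gap to the nearest library, where chance gives about 1 in 20 groups (8.7 here). Of these, 12 belonged to AIS replicate 2.

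AIS replicate 2 lay at -126.69 on the first principal component (others 27.988 to 56.553) and at 130.67 on the third (others -23.155 to 26.331). Its list scores were high for resident fibroblast markers (9.3149 against 7.5875 to 8.2105), smooth muscle markers (9.4487 against 7.3885 to 8.0115), neutrophil markers (7.4399 against 3.0895 to 4.4538) and red blood cell genes (7.4946 against 4.8552 to 5.496). They were low for T cell markers (3.2648 against 5.3755 to 6.6026), adenocarcinoma associated genes (4.6947 against 7.4059 to 8.6879) and cell cycle genes (2.3012 against 5.2794 to 6.0105). As log2 values, AGER was at 12.977 (10.327 to 11.201), CR2 at 0 (4.1214 to 6.4141) and PVT1 at 1.9562 (6.7718 to 7.286).

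Low depth was excluded as the whole cause of this profile, since at 3895038 reads in every AIS library its mean correlation with the others was 0.809, against 0.856 to 0.879 among the rest. A library made from few RNA molecules stays open: 15181 genes had a read at equal depth, against 16447 to 17211, which a different tissue content could give as well. An admixture of normal lung in the captured region may contribute, because 0 of 3 scores (endothelial 8.38, type 1 9.65, adenocarcinoma 4.69) lay within the range of the other 5 AIS libraries and all lay towards the normal means of 8.82, 9.67 and 4.22. It is not shown to be the whole cause, as T cell and cell cycle scores lay below the lowest normal library (4.80 and 2.95), and 11 of 31 list scores were outside the range of the other 11 normal and AIS libraries (another library reached 10, the median library 3). A biological difference of this lesion was not tested.

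The fall of endothelial markers was weighed against technical causes because 23 of 24 passed in invasive tissue. The values argue against a loss of T cells and endothelial cells alike there. The comparison was chosen after the scores were seen, with T cell markers among the lists that did not fall (mean change 0.06). Neutrophil (-2.97), red blood cell (-2.49), smooth muscle (-1.75), resident fibroblast (-1.58), mast cell (-1.21) and macrophage (-0.87) scores fell with the endothelial one (-3.06). Activated fibroblast (0.47), plasma cell (1.05) and B cell (2.38) scores did not. A loss shared by several non-epithelial cell types therefore stays open. In invasive tissue the T cell score change exceeded the endothelial one by 3.11 ± 1.64 (SD, n = 6, 6 of 6 patients, two-sided exact sign flip p = 0.03125, the smallest possible, adjusted p = 0.0417). The macrophage difference did not pass (2.18 ± 1.52, 5 of 6 patients, exact p = 0.0625, adjusted p = 0.0714). In AIS the T cell difference did not pass (1.59 ± 1.54, 5 of 6 patients, exact p = 0.09375), while the macrophage score change exceeded the endothelial one by 1.73 ± 0.72 (6 of 6 patients, exact p = 0.03125, adjusted p = 0.0417). GC content and length bias was excluded as the whole cause, with 23 of 24 markers still lower after its trend was removed, and so were the deposited size factors, with at least 21 lower under quantile, TMM and DESeq2 scaling. A smaller share of vessels in the tumour regions, from capture or from the tissue itself, and lower expression per endothelial cell stay open.

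The rise of B cell markers in invasive tissue rested on 6 of 9 genes. The values argue against a higher share of all lymphocytes alike, again in a comparison chosen after the scores were seen. The B cell score change exceeded the T cell one by 2.32 ± 1.35 (SD, n = 6, 6 of 6 patients, two-sided exact sign flip p = 0.03125, the smallest possible, adjusted p = 0.0417). GC content and length bias was excluded as the whole cause, with 6 markers higher after its trend was removed. No 1 patient made up most of the mean rise of the score, which was at least 71.8% of its value without any 1 of them (2.38 ± 2.40, SD, n = 6; 1.71 to 3.17), but the score was higher in 5 of 6 patients and its own test did not pass (exact sign flip p = 0.0625, adjusted p = 0.121). The number of called markers was not stable, with 2, 3, 1 and 2 without patients 1, 3, 5 and 6, 3 without the patient block and 2 with only the 2 groups in the fit. A candidate explanation that stays open is the capture of lymphoid aggregates in some invasive regions, for which no measure of the tissue sections was used here.

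Other values stood apart singly. Normal replicate 4 had an activated fibroblast score of 8.4148 (others 7.6741 to 7.8769), an immediate early score of 8.8904 (10.422 to 11.305) and an SLC6A4 log2 value of 7.305 (10.477 to 11.576). The nuclear noncoding RNA NEAT1 took 4.6339% of the reads in genes of AIS replicate 5 (0.99341% to 1.5065% in the others). AIS replicate 6 had an activated fibroblast score of 10.48 (7.579 to 8.5565) and AIS replicate 1 a mast cell score of 5.0635 (6.5521 to 7.3741). Invasive replicate 4 had a plasma cell score of 5.2061 (7.1983 to 7.7608). Invasive replicate 6 had scores of 9.3273 for proteases (6.1655 to 7.0686), 9.1016 for epithelial-mesenchymal transition regulators (7.0477 to 7.68) and 8.7546 for hypoxia genes (6.9464 to 7.5301).

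Exchanging the 2 libraries of patients in all 32 ways tested whether chance gave as many calls, the real grouping included. The smallest share possible was 1 of 32, and the shares were not adjusted over the comparisons. A share that small argues against chance and does not exclude it. For AIS against normal 1 of 32 groupings gave as many as the 751 genes, which argues against chance, although another gave 561. For invasive against normal 1 of 32 gave as many as the 1924 genes, which argues against chance by a wider margin (highest other 156). For invasive against AIS the exchanges decide nothing, as any grouping gives at least the real 0 genes in limma (32 of 32, highest other 0), with 667 genes at an unadjusted p under 0.05, 0 calls in edgeR and 11 in DESeq2. Among lincRNAs chance stayed open for AIS against normal (2 of 32 with at least 6 calls, highest other 32). The share argues against chance for lincRNAs in invasive against normal (1 of 32 with at least 79, highest other 5). It was equally small for the single call of invasive against AIS (1 of 32 with 1, highest other 0). That call was lost without 5 of 6 patients and, in limma, without AIS replicate 2. In edgeR without that library linc-EEF1E1-1 passed (adjusted p = 0.0108). Of 99 splits drawn without regard to patients 2 gave 1 call in invasive against AIS, the real one included. For list tests at the preset correlation the share was 1 of 32 in AIS against normal, by a narrow margin (at least 21, highest other 19). Chance stayed open in invasive against normal (4 of 32 with at least 20, highest other 24) and in invasive against AIS (2 of 32 with at least 20, highest other 21). Other groupings gave medians of 11, 14 and 11 called lists, so many calls came without the tissue labels.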

How the results depend on the processing

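The fits without AIS replicate 2 and after removal of GC content and length trends were chosen after the results were seen, and the other settings before. Of the counts of calls 173 stayed within 1.5 times the reported count and 55 did not. Of the list member counts 1067 stayed within it and 445 did not. Of the values of named genes 7433 kept direction and side of the threshold, 499 lost the threshold, 157 gained it and 3 reversed. Named genes that did not pass in the reported fit are among them and could not lose the threshold, so these totals overstate the stability of calls. Of the called list members named, 18 of 51 in AIS and 46 of 77 in invasive tissue passed under every alternative. The cause was not tested except where fewer patients or genes entered. At the depth reached (2226704 to 12563143 reads), the simulated comparison of invasive with normal tissue recovered 10.9% of 2-fold and 66.0% of 4-fold changes. Changes of that size may therefore be missed, although some smaller ones passed. The shares do not carry over to the real comparison, which had 1924 calls among 14758 genes, against 128 among 14394 simulated ones. With fewer changed genes the adjusted threshold is stricter.

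The pairing of libraries by patient moved several counts. With no replicate block 180 genes passed for AIS and 854 for invasive tissue against normal, each also called with the block, and 45 lincRNAs for invasive tissue. With the patient as a random effect 2 genes passed between invasive tissue and AIS and 2 in order over the 3 types. The block changed no other count of called genes, lincRNAs or lists by over 1.5 times, while counts of list members moved more often.

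Leaving out each patient gave 237 to 1487 genes for AIS, 1134 to 2061 for invasive tissue and 0 to 1 between them, 0 to 37, 42 to 90 and 0 to 1 lincRNAs in the same order, 16 to 21, 18 to 21 and 13 to 20 lists, and 0 to 1 ordered genes. AIS calls moved by over 1.5 times without patient 1 (346 genes), 2 (1487), 3 (237) or 5 (273), invasive calls without patient 3 (1134) or 5 (1235), and the lists between invasive tissue and AIS without patient 2 (13). Without AIS replicate 2 alone there were, in limma, 1377 genes and 38 lincRNAs for AIS, 2449 and 100 for invasive tissue, and 0 lincRNAs between invasive tissue and AIS. In edgeR without it there were 1277 genes and 31 lincRNAs for AIS, and linc-EEF1E1-1 passed between invasive tissue and AIS (adjusted p = 0.0108). FAP between invasive tissue and AIS turned from 0.90 (up to 1.25 without patient 1) to -0.12 without that library in limma and -0.0299 in edgeR, and ZEB2 from -0.23 to 0.0585 in edgeR. Neither passed the threshold in the reported fit.

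By other settings, DESeq2 gave 1736 genes and 48 lincRNAs for AIS, 125 lincRNAs for invasive tissue, 11 genes and 4 lincRNAs (linc-C3orf30-6, linc-BTN1A1-1, linc-EEF1E1-1, linc-TIMM22-1) between them and 7 ordered genes. The fitted value of linc-BTN1A1-1, -20.6, is too large to be read as a measured change. Library weights gave 1424 genes and 48 lincRNAs for AIS and 3 lincRNAs (linc-EEF1E1-1, linc-RECK-3, linc-COX4NB-9) between invasive tissue and AIS. For AIS lincRNAs quantile normalization gave 32, a pseudocount of 5 gave 10 and no filter gave 0 (439 at an unadjusted p). For invasive lincRNAs no filter gave 45, a mean of at least 50 gave 33 and edgeR gave 46 with either scaling. The 1 lincRNA call between invasive tissue and AIS became 0 with a pseudocount of 5, only the 2 groups, quantile normalization and FPKM values. With a mean of at least 50 the count was 0 as well. There linc-EEF1E1-1 (means of 92.7 in normal lung, 30.0 in AIS and 0.448 in invasive tissue) fell below the filter and was not tested. With an estimated correlation 0 lists passed for AIS, invasive tissue and between them, against 21, 20 and 20, with 7, 9 and 3 at an unadjusted p and 10, 14 and 0 by fry. Recomputed DESeq2 size factors differed from the deposited ones by up to 34.7%.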

Other observations

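The scan of gene families by symbol, and the genes named from it, were chosen after the data were seen, while the test of lincRNAs against the genes whose symbols they carry was chosen before its result was seen. Genes were put in a family by the letters before the first digit of the symbol, so relatives with further letters there were left out. Of 239 families with at least 8 tested members, 1 of 956 Fisher's exact tests passed adjustment, and genes of a family are not independent replicates. It concerned protocadherins, adhesion molecules of the cadherin superfamily, with a digit straight after PCDH in the symbol. Of these, 7 of 11 fell in invasive tissue (PCDH1, PCDH10, PCDH12, PCDH15, PCDH17, PCDH18 and PCDH9), against 9.11% of all genes (Fisher's exact test, one-sided, p = 1.22e-05, adjusted p = 0.0117, median log2 change -1.44 over the 11). PCDH12 encodes an adhesion protein of endothelial cells, whose markers also fell. The number of these protocadherins called lower was 6 or 7 under the other scalings and the FPKM table, all with a median below 0, 5 without patient 3 or 5, and 2 without the patient block. The KLF transcription factors came next with 7 of 15 lower in invasive tissue (adjusted p = 0.0819 by Fisher's exact test). Integrin alpha genes with a digit straight after ITGA followed, with 4 of 11 lower in AIS (ITGA1, ITGA5, ITGA6 and ITGA8, adjusted p = 0.0889 by the same exact test). Neither family passed.

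The hypothesis that lincRNAs change together with the gene whose symbol they carry was tested across 707 pairs, after leaving out 41 lincRNAs whose values followed those of a gene. For invasive against normal tissue the log2 changes correlated with r = 0.159 (rho = 0.172, permutation p = 0.0001, the smallest that 10000 shuffles can give), and 397 pairs (56.2%) shared a sign. For AIS the values were r = 0.107 and permutation p = 0.0046. Of 55 called lincRNAs with a tested gene 9 were called the same way as the gene and 0 the other way. The relation was weak and across transcripts, which are not independent replicates. Joint regulation may give such a relation, and so may reads or transcription running past a gene's end, which were not tested.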
